A study of Mus musculus with 6 samples.

How the data were processed

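The data were RNA-seq expression values of a mouse trophoblast stem cell line, the self-renewing cells from which the placental lineages form. The 6 libraries fell into 3 groups of 2. The first group was grown in standard trophoblast stem cell medium. The second was grown in the same medium without bFGF, the fibroblast growth factor on which these cells depend. The third was also grown without bFGF and was forced to express ectopic Esrrb, an orphan nuclear receptor. Groups and replicate numbers were taken from the labels. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. They name no empty-vector control either, so ectopic Esrrb and its delivery were not separated by the design. Per the labels, mRNA was enriched on oligo(dT) beads, fragmented, copied with random hexamers and sequenced on an Illumina HiSeq instrument as read pairs.

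Reads were handled with TopHat2 2.0.12 and Cufflinks 1.2.0 on the mm9 mouse genome, per the submitters' processing notes. The deposited tables held FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) for 28842 RefSeq transcripts in each library, with positions and a status, per the file headers. The deposited coverage signal per transcript was used only to describe depth. FPKM is normalized by the authors to transcript length and library size, so a large change in a few abundant genes shifts all other genes of that library. Total FPKM ran from 447663 to 502207 per library. All 28842 transcripts had an OK status in all files. Solving the FPKM formula gave about 9560000 and 14170000 fragments for standard medium, 13610000 and 13770000 without bFGF and 13040000 and 11830000 with ectopic Esrrb. Whole fragments could not be recovered. Of the values worth 4 to 10 fragments, 73.7% to 77.4% per library came out whole within 0.05, and of those worth 50 to 200 only 31.5% to 33.7% did. No model of read counts was therefore used, and low values carry an unknown counting error. Cufflinks divides reads among transcripts and similar copies by estimation. Values of near-identical families, such as the Rhox6 and Rhox9, Serpinb9, placental cathepsin, prolactin, ribosomal protein and histone genes, are therefore uncertain, as are overlapping genes and genes with an antisense partner. How strand was used is not given in the sources used here.

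FPKM of transcripts with the same symbol was summed, which gave 22517 genes, 3659 of them with several transcripts. Transcripts without a symbol (637) were left out of the tests and held 1.602% to 2.502% of a library's FPKM. No mitochondrial transcripts were listed. Positions are those of the deposited files, on mm9; the deposited starts are counted from 0, as the lengths of single-exon transcripts showed, and were raised by 1 so that printed positions are counted from 1; the reference genome at hand is another build, and none of its coordinates were used. The 22517 genes were filtered to 11422 with FPKM of at least 1 in at least 2 libraries. Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. A linear model with 1 mean per group was fitted to all 6 libraries with limma, with moderated variances that follow the mean, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p below 0.05. The fit has 3 residual degrees of freedom. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so single genes had no such test. Replicates correlated across genes with r = 0.995, 0.994 and 0.996 in the 3 groups, and each library was counted as 1 sample, as the labels list it.

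The 3 comparisons, their tests, 26 gene lists and the rule for named genes were fixed before the data were examined. The lists covered trophoblast stem cell self-renewal, trophoblast giant cells, spongiotrophoblast and glycogen cells, syncytiotrophoblast and labyrinth, FGF and ERK response, mitosis, DNA replication, CDK inhibitors and endocycle, embryonic stem cell pluripotency, primitive endoderm, fibroblasts and feeder cells, epithelial genes, mesenchymal transition, oxidative phosphorylation and TCA cycle, steroid hormone synthesis, cholesterol synthesis, glycolysis and hypoxia, imprinted genes, activin, TGF-beta and BMP response, Wnt response, interferon response, stress and unfolded protein response, immediate early genes, blood and endothelium, cytosolic ribosomal proteins, and histones. Each was tested against all other genes with camera (limma), with a preset correlation of 0.01 between genes, and its p was adjusted over the 26 lists. Counts are given over tested members only, and in several lists many members did not reach the expression filter. Tested were 9 of 28 listed spongiotrophoblast and glycogen cell genes, 16 of 25 giant cell genes, 6 of 25 fibroblast genes and 7 of 18 blood and endothelium genes. A gene expressed in 1 group only could pass this filter. Calls with an estimated correlation and the fry test were alternatives. With an estimated correlation camera is limited to the 3 residual degrees of freedom of the fit, so a list can hardly pass whatever its correlation. Such p-values are printed for completeness and do not show that correlation between genes explains a list. List medians are given after subtraction of the median of all tested genes. Reversal was counted over genes that changed at least 2-fold without bFGF: a gene moved back if it changed the other way with ectopic Esrrb. Because both comparisons used the no bFGF libraries, 100 draws of unchanged groups were simulated to show what this sharing alone gives. The number of genes that independent lists would share is given beside it.

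Named genes were 12 genes fixed in advance (Esrrb, Cdx2, Eomes, Elf5, Sox2, Tfap2c, Hand1, Prl3d1, Prl2c2, Tpbpa, Gcm1 and Syna). Added were the 10 rises and 10 falls with the largest log2 change per comparison at a mean of at least 5 FPKM and with replicates that did not overlap. The 10 largest changes back in each direction were also named. From each list in each comparison came the 4 members with the smallest p and, beside them, up to 2 changed members in either direction. Predicted genes were skipped, and not all were printed. Outside this rule, chosen after their values were seen, stand the neighbours of Surf1 and Surf2, the Esrp genes, Fgfr2, Slk, Mprip, the leukocyte genes beside the interferon list, and Arhgef16, Pcsk6, Scube3 and Spsb4 where they are named with genes lost or gained with ectopic Esrrb.

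Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, quantile normalization, scaling by median ratios, only the highest transcript per symbol, variances without the trend or robust, only the groups compared, a stricter adjusted p of 0.01, the replicate number as a block, and each library left out in turn. Whether the numbers pair the libraries was checked from their deviations. On simulated data with 200 changed genes among 11422, limma found 97% of changes of 0.5 and 100% of changes of 1 on the log2 scale in the first comparison, with 13 false among 210 calls. In the second it found 95% and 100%, with 18 false among 213, and in the third 92% and 99%, with 9 false among 200. A list shifted by 0.5 was called in 20 of 20 runs with 0 of the other 25 lists called, and a reversal of 50% of genes came back as 47.1%. The simulated noise was independent between genes, and all other genes were unchanged in the list runs. The runs therefore do not show how often lists of correlated genes are called falsely. In the data the estimated correlation reached 0.690, for ribosomal proteins. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.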

Results

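Gene expression was measured by RNA-seq in 6 libraries of mouse trophoblast stem cells. There were 2 libraries from standard medium, 2 from medium without bFGF, and 2 from medium without bFGF after forced expression of ectopic Esrrb. The libraries held about 9560000 to 14170000 fragments, and between 10548 and 10768 genes reached 1 FPKM in each. The translation elongation factor gene Eef1a1 had the highest value in all 6. Along the first principal component, which held 68.5% of the variance, and the second, with 28.5%, libraries separated by group. Values below are FPKM as mean ± SD (n = 2), and a gene is said to rise or fall only where its limma adjusted p was below 0.05.

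Esrrb itself, at chromosome 12, 87702067 to 87862578 (mm9), was listed at 81.3 and 83.0 FPKM in standard medium, at 0.262 and 0.259 FPKM without bFGF, and at 67.6 and 68.5 FPKM with ectopic Esrrb. The low level without bFGF set that group apart. The levels of the other groups lay too close together for Esrrb to check which of them carried the ectopic gene. The Esrrb level with the ectopic gene was slightly below that of standard medium (log2 fold change -0.27, limma adjusted p = 0.0016). FPKM does not separate transcripts of the ectopic gene from those of the cells' own gene.

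**Figure D1:**
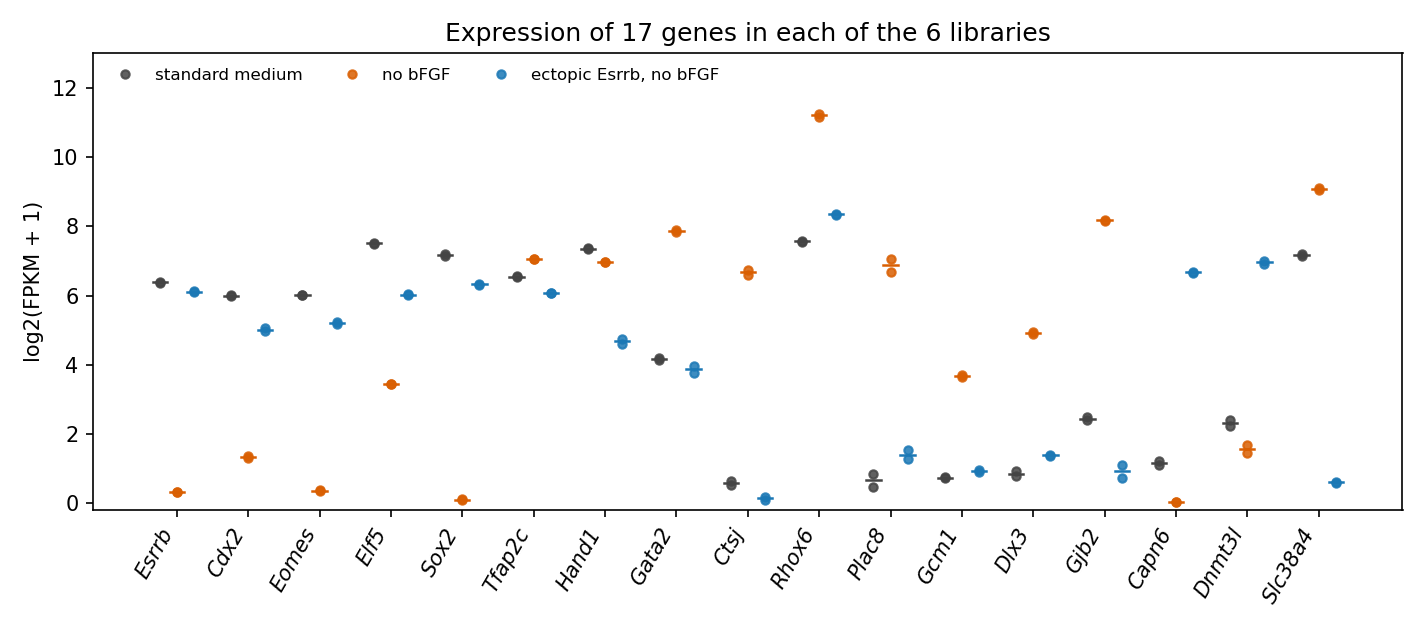
FPKM of 17 genes in each of the 6 libraries, plotted as log2(FPKM + 1); each point is 1 library, each short line a group mean, and colours mark the 3 groups. Esrrb, Cdx2, Eomes, Elf5 and Sox2 lay lowest without bFGF, Gata2, Ctsj, Rhox6, Plac8, Gcm1, Dlx3 and Gjb2 lay highest there, and Capn6 and Dnmt3l lay highest with ectopic Esrrb.

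The first comparison asked what the loss of bFGF did to the cells. Most trophoblast stem cell self-renewal genes fell, some of them to near 0 (18 of 22 members, adjusted p = 0.199 with an estimated correlation). Sox2 went from 142 ± 4.9 to 0.077 ± 0.022 FPKM, Eomes from 63.8 ± 0.27 to 0.287 ± 0.016 FPKM, and Cdx2 from 62.6 ± 0.81 to 1.53 ± 0.091 FPKM. Several genes of differentiated trophoblast rose at the same time: Plac1, a placental gene, went from 2.08 ± 0.44 to 203 ± 4.3 FPKM, and Gjb2, the labyrinth connexin 26 gene, from 4.44 ± 0.24 to 288 ± 2.9 FPKM. Most epithelial, imprinted and interferon response genes also rose, while most genes of mitosis and of the response to FGF fell. These lists passed camera with a preset correlation, and none of them did with an estimated correlation (adjusted p from 0.143 to 0.413 with an estimated correlation). The latter rests on 3 residual degrees of freedom and could hardly call any list.

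In all, 8908 of the 11422 tested genes changed by limma at an adjusted p below 0.05 (9052 at an unadjusted p below 0.05), 3770 higher and 5138 lower. At least 2-fold changes were found in 2268 genes, 1044 higher and 1224 lower. Both splits depended on scaling. They were 4258 higher and 4670 lower, and 1182 and 1056 at 2-fold, under quantile normalization, and 4429 and 4532, and 1223 and 1048 at 2-fold, under median scaling. The median change of all genes was -0.11 on the log2 scale, and list medians below are relative to it. Of the self-renewal list, 18 of 22 tested members fell and 4 rose (median -2.09). Elf5, an ETS factor of the stem cell state, fell from 180 ± 2.9 to 9.92 ± 0.034 FPKM, and Id2, an inhibitor of bHLH factors, from 438 ± 3.1 to 13.9 ± 0.42 FPKM. The members that rose included Ets2, with 25.9 ± 0.24 and 66.7 ± 1.8 FPKM, and Tfap2c, an AP-2 factor, with 92.2 ± 0.99 and 132 ± 0.64 FPKM (log2 fold change 0.51, limma adjusted p = 6.3e-06). The list passed camera with an adjusted p of 5.95e-05 and had an adjusted p = 0.199 with an estimated correlation.

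The FGF and ERK response list fell in 21 of 24 members and rose in 3 (median -2.64, camera adjusted p = 1.22e-05, adjusted p = 0.143 with an estimated correlation). Of this list Spry2, Dusp6 and Etv4 were among the 10 largest falls by the rule for named genes. Spry2, a feedback inhibitor of the pathway, fell from 62.5 ± 1.6 to 0.331 ± 0.002 FPKM, the ERK phosphatase gene Dusp6 from 40.4 ± 0.37 to 0.214 ± 0.11 FPKM, and the ETS factor Etv4 from 36.7 ± 1.8 to 0.114 ± 0.024 FPKM. Duox2, which encodes a hydrogen peroxide-producing oxidase, fell from 35.0 ± 0.47 to 0.056 ± 0.034 FPKM, and Zic2, a zinc finger factor, from 49.7 ± 1.1 to 0.050 ± 0.035 FPKM. Of the activin, TGF-beta and BMP list, 12 of 19 fell and 3 rose (median -0.42, camera adjusted p = 0.0488, adjusted p = 0.540 with an estimated correlation). Bmp4, a ligand made by the stem cells' lineage in the embryo, was among them at 49.0 ± 2.2 and 0.812 ± 0.16 FPKM.

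Giant cell genes rose in 13 of 16 tested members and fell in 3 (median 3.65, camera adjusted p = 3.66e-05, adjusted p = 0.143 with an estimated correlation). Ctsj, a placental cathepsin, went from 0.497 ± 0.084 to 101 ± 7.4 FPKM, and the homeobox gene Rhox6 from 188 ± 0.93 to 2355 ± 99 FPKM. Gata2, a regulator of placental hormone genes, went from 16.9 ± 0.39 to 232 ± 4.0 FPKM. Hand1, a factor of giant cell formation, fell from 162 ± 1.5 to 124 ± 1.2 FPKM, and Mmp9, a matrix protease gene, from 8.82 ± 0.32 to 0.934 ± 0.010 FPKM. Prl3d1, placental lactogen I, went from 0.306 ± 0.29 to 1.68 ± 0.51 FPKM. Prl2c2 was listed at 0 in all libraries of the other groups and did not reach the expression filter, and neither did Tpbpa, a spongiotrophoblast gene. Leaving out no bFGF replicate 1 or 2 ended the giant cell call (camera adjusted p = 0.42 and 0.332), with genes expressed only in that group then failing the filter of 2 libraries.

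Of the syncytiotrophoblast and labyrinth list, 17 of 19 members rose and 1 fell (median 2.10, camera adjusted p = 3.32e-07, adjusted p = 0.143 with an estimated correlation). Dlx3, a labyrinth homeobox gene, went from 0.819 ± 0.13 to 29.3 ± 0.98 FPKM. Gcm1, the factor of labyrinth branching, went from 0.673 ± 0.031 to 11.8 ± 0.44 FPKM, and Syna, the fusion protein syncytin A, from 0.074 ± 0.001 to 2.97 ± 0.24 FPKM. Of 28 listed spongiotrophoblast and glycogen cell genes only 9 reached the expression filter. Of these 9, 7 rose and 2 fell (median 1.59, camera adjusted p = 0.00684, adjusted p = 0.199 with an estimated correlation). Ascl2, which the ectoplacental cone needs, went from 3.73 ± 0.097 to 26.8 ± 1.2 FPKM and Plac8 from 0.603 ± 0.29 to 117 ± 23 FPKM. This call also ended without no bFGF replicate 1 (camera adjusted p = 0.191) or 2 (0.142).

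The mitosis list fell in all 28 members (median -0.83, camera adjusted p = 6.85e-08, adjusted p = 0.143 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 91.0 ± 0.70 to 29.3 ± 0.29 FPKM, and the centromeric histone gene Cenpa from 69.0 ± 0.44 to 24.5 ± 0.42 FPKM. DNA replication genes fell in 23 of 29 and rose in 4 (median -0.47, camera adjusted p = 0.00231, adjusted p = 0.540 with an estimated correlation). Among them Rrm2, a subunit of ribonucleotide reductase, fell from 165 ± 2.5 to 64.5 ± 1.4 FPKM, while the cyclin gene Ccne2 rose from 5.49 ± 0.27 to 11.1 ± 0.17 FPKM. The CDK inhibitor gene Cdkn1c, imprinted and known from giant cell endocycles, rose from 36.0 ± 0.63 to 510 ± 8.4 FPKM. Its list of CDK inhibitors and endocycle genes was not past the threshold (6 of 12 rose, 4 fell, camera adjusted p = 0.322).

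Epithelial genes rose in 17 of 22 and fell in 3 (median 1.34, camera adjusted p = 2.81e-05, adjusted p = 0.413 with an estimated correlation). The keratin genes Krt8, at 419 ± 5.1 and 2514 ± 144 FPKM, and Krt19, at 80.4 ± 2.2 and 680 ± 22 FPKM, had some of the highest levels of the list. Imprinted genes rose in 17 of 21 and fell in 3 (median 1.01, camera adjusted p = 3.29e-05, adjusted p = 0.281 with an estimated correlation). Peg10, a retrotransposon-derived placental gene, went from 289 ± 6.3 to 2074 ± 51 FPKM and the growth factor gene Igf2 from 503 ± 4.7 to 2161 ± 7.1 FPKM, while Mest fell from 88.4 ± 0.50 to 3.81 ± 0.047 FPKM. All 18 tested interferon response genes rose (median 2.35, camera adjusted p = 8.77e-09, adjusted p = 0.143 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 1.70 ± 0.14 to 35.9 ± 2.4 FPKM and the antiviral gene Rsad2 from 0.173 ± 0.048 to 11.6 ± 0.16 FPKM. Among leukocyte genes measured beside them, Laptm5, a lysosomal membrane protein gene and the most abundant in standard medium only, fell from 41.7 ± 3.2 to 2.78 ± 0.25 FPKM. Csf1r, the receptor of a macrophage growth factor, went from 1.07 ± 0.25 to 10.1 ± 0.63 FPKM, and Tyrobp was listed at 0 in all 6 libraries.

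Cytosolic ribosomal protein genes fell in 29 of 31 (median -0.40, camera adjusted p = 3.29e-05, adjusted p = 0.540 with an estimated correlation), with Rps4x at 2354 ± 103 and 1214 ± 79 FPKM. Steroid hormone genes rose in 6 of 10 and fell in 1 (median 0.44, camera adjusted p = 0.0261, adjusted p = 0.257 with an estimated correlation); Cyp17a1, an androgen-forming enzyme gene, went from 0.020 ± 0.029 to 7.32 ± 1.1 FPKM. The fibroblast and feeder list rose in 5 of 6 (median 0.76, camera adjusted p = 0.0488, adjusted p = 0.358 with an estimated correlation), at low levels such as 0.876 ± 0.014 and 2.71 ± 0.16 FPKM of the collagen gene Col1a1. Oxidative phosphorylation and TCA cycle genes rose in 14 of 32 and fell in 6 (median 0.21, camera adjusted p = 0.0488, adjusted p = 0.734 with an estimated correlation), among them the cytochrome oxidase gene Cox5b at 305 ± 5.3 and 490 ± 15 FPKM. The steroid call ended without no bFGF replicate 1 (camera adjusted p = 0.127) or 2 (0.142), and at a mean of at least 5 FPKM (0.238). The calls of the fibroblast, oxidative phosphorylation and activin lists ended without no bFGF replicate 2 (0.0637, 0.142 and 0.0735), without ectopic Esrrb replicate 1 (0.0611, 0.0611 and 0.0509) and without its replicate 2 (0.0613, 0.0613 and 0.0507). Those of fibroblasts and activin also ended without no bFGF replicate 1 (0.0915 and 0.0710), and those of fibroblasts and oxidative phosphorylation without standard medium replicate 2 (0.0627 and 0.106). Under quantile normalization the oxidative phosphorylation list did not pass (0.160).

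The remaining 10 lists, besides that of CDK inhibitors, did not pass, with camera adjusted p from 0.139 to 0.943. They were embryonic stem cell pluripotency, primitive endoderm, mesenchymal transition, cholesterol synthesis, glycolysis and hypoxia, Wnt response (0.00473 at a mean of at least 5 FPKM), stress, immediate early genes, blood and endothelium, and histones. For cholesterol synthesis and for blood and endothelium the median lay below 0 and the camera direction above it. Of the 26 lists, 15 passed and 0 did with an estimated correlation. Counts of members adjusted over the list alone were the same as over all genes in 25 of 26 lists and differed by at most 1 gene.

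**Figure D2:**
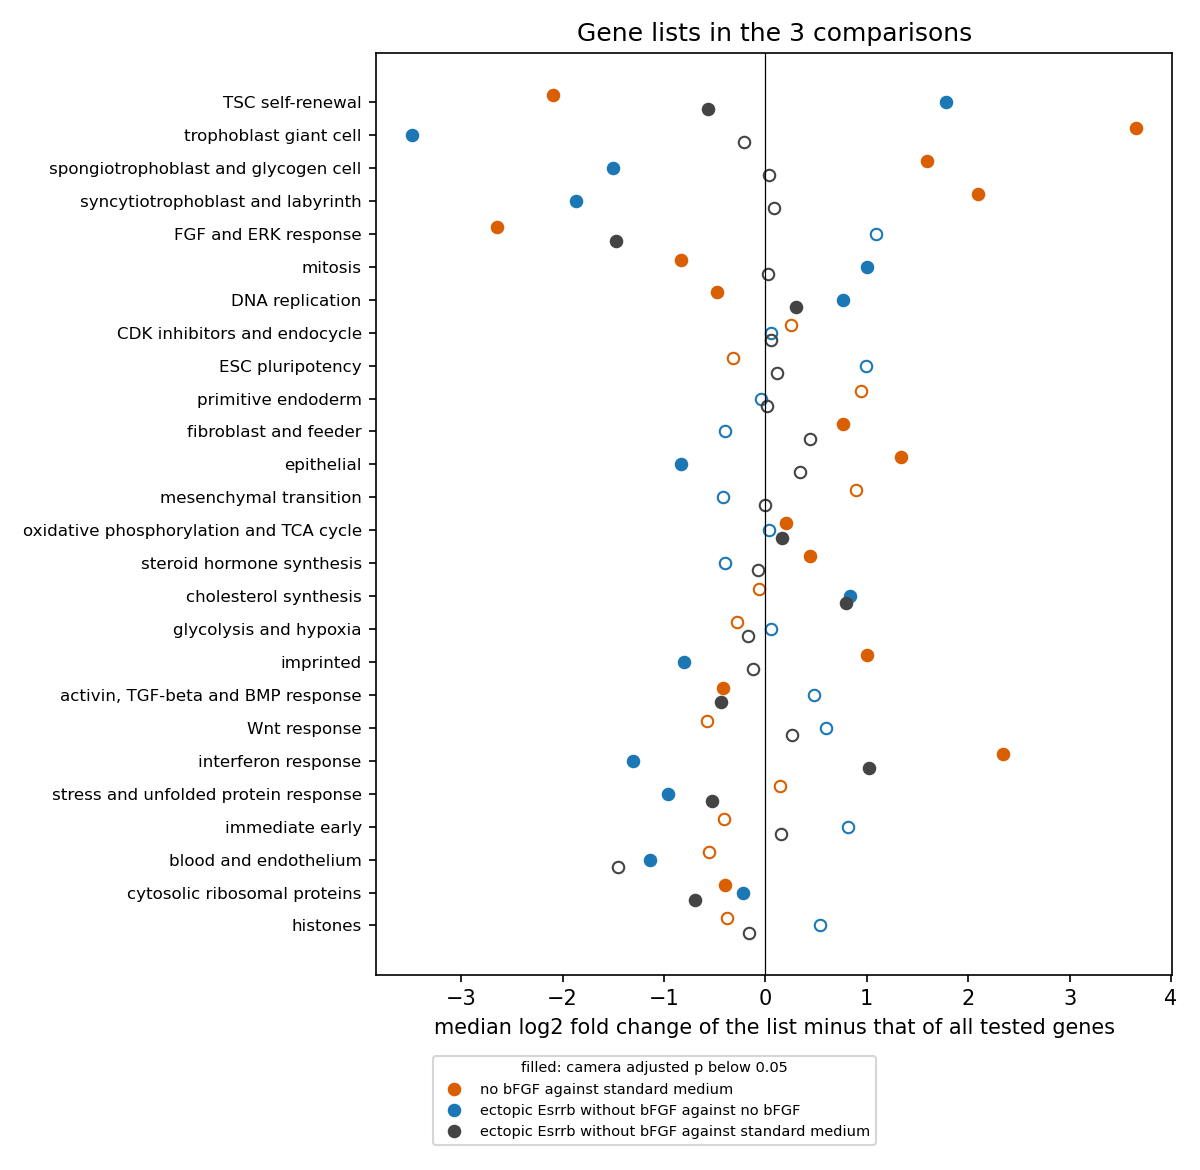
Median log2 fold change of each of the 26 gene lists minus that of all tested genes, in the 3 comparisons (colours); filled points passed camera at an adjusted p below 0.05 and open points did not. Giant cell genes lay at 3.65 without bFGF and at -3.48 when ectopic Esrrb was set against no bFGF, FGF and ERK response genes at -2.64 without bFGF and at -1.48 when ectopic Esrrb was set against standard medium, and the point of ribosomal proteins in the comparison with no bFGF changed direction under quantile normalization.

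The second comparison asked what forced Esrrb expression changed in cells without bFGF. Several stem cell factors rose: Sox2 reached 78.8 ± 1.5 FPKM against 0.077 ± 0.022 FPKM without the ectopic gene, Eomes 36.0 ± 0.90 against 0.287 ± 0.016 FPKM, and Id2 398 ± 15 against 13.9 ± 0.42 FPKM. Several placental genes fell, with Gjb2 at 0.915 ± 0.36 against 288 ± 2.9 FPKM and Plac1 at 4.56 ± 0.32 against 203 ± 4.3 FPKM. Most mitosis, DNA replication and cholesterol synthesis genes were higher with ectopic Esrrb, and most giant cell, labyrinth, epithelial, imprinted, interferon and stress genes were lower. These lists passed camera with a preset correlation, and none of them did with an estimated correlation (adjusted p from 0.175 to 0.377 with an estimated correlation).

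By limma, 9113 genes changed at an adjusted p below 0.05 (9254 at an unadjusted p below 0.05), 5856 higher and 3257 lower, and 2479 changed at least 2-fold, 1497 higher and 982 lower. The split depended on scaling, since the median change of all genes was 0.21 on the log2 scale. It was 4892 higher and 4183 lower under quantile normalization, and 4532 and 4515 under median scaling. The 2-fold changes then split into 1071 and 1236, and 1020 and 1321. Capn6, a calpain-like gene of the placenta at chromosome X, 140236780 to 140261955 (mm9), had the largest rise, from 0.021 FPKM to 100 ± 1.4 FPKM (log2 fold change 6.64, limma adjusted p = 7.2e-10). Dnmt3l, the cofactor of de novo DNA methyltransferases, rose from 1.98 ± 0.32 to 123 ± 5.0 FPKM. Foxh1, a nuclear partner of nodal signalling, rose from 0.892 ± 0.39 to 56.6 ± 1.1 FPKM, and the surface antigen gene Ly6a from 0.219 ± 0.16 to 60.3 ± 1.9 FPKM. The largest fall was that of Slc38a4, an imprinted amino acid transporter gene, from 540 ± 13 to 0.533 ± 0.021 FPKM (log2 fold change -8.46, limma adjusted p = 1.5e-11).

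Of the self-renewal list, 17 of 22 members rose and 5 fell (median 1.78, camera adjusted p = 0.00717, adjusted p = 0.377 with an estimated correlation). Esrrb, the forced gene, is among the members that rose and was not left out of the test, though the design set its rise. Cdx2 reached 31.2 ± 1.5 FPKM and Elf5 64.0 ± 1.2 FPKM, while Tfap2c fell to 66.4 ± 0.34 FPKM and Ets2 to 20.2 ± 0.038 FPKM. Of the FGF and ERK response list, 16 of 24 members rose and 4 fell, and the list was not past the threshold (camera adjusted p = 0.0584), though it was under quantile normalization (0.0207), median scaling (0.0085), with no filter (0.0082), and without ectopic Esrrb replicate 1 (0.0422) or 2 (0.0293). The immediate early transcription factor gene Egr1, a target of ERK signalling, rose from 2.91 ± 0.23 to 57.7 ± 0.090 FPKM.

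The giant cell list fell in 14 of 16 members and rose in 2 (median -3.48, camera adjusted p = 5.74e-07, adjusted p = 0.175 with an estimated correlation). Without no bFGF replicate 1 its adjusted p was 0.0537. Ctsj fell to 0.105 ± 0.043 FPKM, Rhox9 from 586 ± 49 to 25.8 ± 1.3 FPKM, and Hand1 to 24.7 ± 1.7 FPKM. Spongiotrophoblast and glycogen cell genes fell in 7 of 9 and rose in 1 (median -1.50, camera adjusted p = 0.00217, adjusted p = 0.175 with an estimated correlation), with adjusted p = 0.128 without no bFGF replicate 1 and 0.116 without replicate 2. Syncytiotrophoblast and labyrinth genes fell in 16 of 19 and rose in 2 (median -1.87, camera adjusted p = 2.34e-06, adjusted p = 0.175 with an estimated correlation). Gcm1 fell to 0.920 ± 0.064 FPKM and Dlx3 to 1.61 ± 0.045 FPKM, while Met, the receptor of hepatocyte growth factor, rose from 0.804 ± 0.060 to 6.97 ± 0.35 FPKM.

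All 28 mitosis genes rose (median 1.00, camera adjusted p = 3.6e-07, adjusted p = 0.175 with an estimated correlation), with Cenpa at 76.5 ± 1.3 FPKM and Cdc20 at 82.4 ± 1.8 FPKM. DNA replication genes rose in 26 of 29 and fell in 2 (median 0.76, camera adjusted p = 9.47e-05, adjusted p = 0.377 with an estimated correlation). Mcm4, part of the replicative helicase, rose from 23.6 ± 0.71 to 66.2 ± 0.77 FPKM, and the cyclin genes Ccne1 and Ccne2 were the 2 that fell. Cholesterol synthesis genes rose in 17 of 19 and fell in 2 (median 0.84, camera adjusted p = 0.00217, adjusted p = 0.377 with an estimated correlation). Dhcr24, the enzyme that reduces the sterol side chain, rose from 16.5 ± 0.90 to 62.3 ± 1.4 FPKM and the isoprenoid isomerase gene Idi1 from 9.65 ± 0.39 to 32.5 ± 0.90 FPKM, while the LDL receptor gene Ldlr fell from 120 ± 5.4 to 44.3 ± 1.1 FPKM.

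Epithelial genes fell in 16 of 22 and rose in 4 (median -0.83, camera adjusted p = 3.64e-05, adjusted p = 0.377 with an estimated correlation), with Krt8 at 606 ± 3.6 FPKM. Imprinted genes fell in 13 of 21 and rose in 4 (median -0.80, camera adjusted p = 9.98e-04, adjusted p = 0.377 with an estimated correlation). Cdkn1c fell to 17.2 ± 0.11 FPKM and Peg10 to 258 ± 3.8 FPKM. Interferon response genes fell in 15 of 18 and rose in 2 (median -1.31, camera adjusted p = 8.87e-05, adjusted p = 0.175 with an estimated correlation). Isg15 fell to 10.1 ± 0.25 FPKM, and the members that rose were Ifih1, a sensor of double-stranded RNA, from 5.45 ± 0.050 to 17.6 ± 0.29 FPKM, and Gbp2, a guanylate-binding protein gene, from 7.61 ± 0.036 to 12.9 ± 1.4 FPKM. Stress and unfolded protein response genes fell in 17 of 25 and rose in 4 (median -0.96, camera adjusted p = 3.59e-05, adjusted p = 0.377 with an estimated correlation). Sesn2, a stress-induced inhibitor of mTORC1, fell from 55.0 ± 2.3 to 13.2 ± 0.33 FPKM.

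The blood and endothelium list fell in all 7 tested members (median -1.14, camera adjusted p = 0.00124, adjusted p = 0.175 with an estimated correlation), among them Cdh5, the cadherin of endothelium, from 14.7 ± 0.076 to 0.486 ± 0.005 FPKM. Ribosomal protein genes fell in 11 of 31 and rose in 6 (median -0.22, camera adjusted p = 0.0306, adjusted p = 0.772 with an estimated correlation). That direction turned upward under quantile normalization (adjusted p = 0.921), and the call ended without no bFGF replicate 2 (0.0945) and with no filter (0.0528). A further 12 lists did not pass, with camera adjusted p from 0.159 to 0.719: CDK inhibitors, pluripotency, primitive endoderm, fibroblasts, mesenchymal transition, oxidative phosphorylation, steroid hormones, glycolysis, activin, Wnt (0.0471 at a mean of at least 5 FPKM), immediate early genes and histones. For CDK inhibitors the median lay 0.056 above that of all genes and the camera direction was down. In total 13 lists passed, 0 with an estimated correlation, and counts adjusted over the list alone were the same in 24 of 26 lists, with a difference of at most 1 gene.

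The reversal comparison asked how far expression with ectopic Esrrb lay back towards standard medium. The 3 groups gave no time order, so these genes may never have changed in the cells with ectopic Esrrb. Of the genes at least 2-fold lower without bFGF, 89.5% were higher with ectopic Esrrb than without it. Under the rule for named genes these were led by Capn6, Sox2, Esrrb, Ly6a and Foxh1. Capn6 was at 1.25 FPKM in standard medium, 0.021 without bFGF and 100 with ectopic Esrrb, so it rose far beyond standard medium. Esrrb was the forced gene, so its rise does not show a return. Of the genes at least 2-fold higher without bFGF, 91.2% were lower with ectopic Esrrb, led under the same rule by Slc38a4, Gjb2, Ctsj, Serpinb9e and Arhgef6. Arhgef6, a guanine nucleotide exchange factor gene, was at 0.895 ± 0.025 FPKM in standard medium, 73.2 ± 3.0 without bFGF and 0.520 ± 0.19 with ectopic Esrrb.

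Among 1224 lower genes, 1095 moved back, 36 moved further and 93 did neither. The median recovery was 77.0% of the log2 change (quartiles 47.0% and 106%), and 711 (58.1%) were still lower than in standard medium. Among 1044 higher genes, 952 moved back, 31 moved further and 61 did neither, with a median recovery of 81.5% (quartiles 49.6% and 102%) and 577 (55.3%) still higher. A further 229 lower genes ended above standard medium and 142 higher genes ended below it. Independent lists would share 628 of the 1224 and 298 of the 1044 genes, since the second comparison called most genes. Simulated unchanged groups that shared the no bFGF libraries gave 0.00722% and 0.00666% back. Those shares were near 0 by construction, because almost no gene can be called between unchanged groups, and are no base for the observed ones. Across genes, which are not independent replicates, the covariance of the 2 log2 changes was -0.676 against -0.0045 in simulation, a difference of -0.672. The small simulated covariance argues against noise in the shared libraries as the source of most of this difference. Shares with genes picked in 1 no bFGF library and measured against the other are given with the processing settings below. The no bFGF group could not be divided with 2 libraries in each part, so what both of its libraries have in common was not separated.

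**Figure D3:**
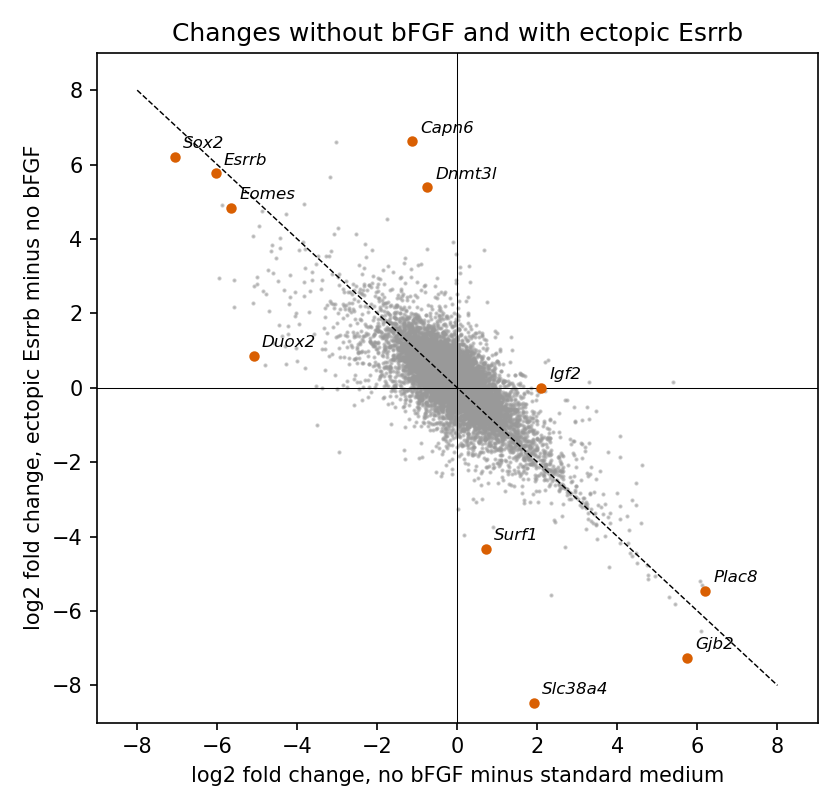
Log2 fold change of each of the 11422 tested genes without bFGF (horizontal axis) and with ectopic Esrrb against no bFGF (vertical axis); each grey point is 1 gene, named genes are orange, and the dashed line marks a full return. Genes spread along the dashed line, while Capn6 and Dnmt3l lie far above it and Slc38a4 and Surf1 far below it. Igf2 lies near the horizontal line of no change with Esrrb, and Duox2 somewhat above that line but far from a full return.

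The third comparison asked how cells held by ectopic Esrrb without bFGF differed from cells in standard medium. They had several stem cell factors at part of their usual level, with Sox2 at 78.8 ± 1.5 against 142 ± 4.9 FPKM and Cdx2 at 31.2 ± 1.5 against 62.6 ± 0.81 FPKM. Most FGF response genes were lower than in standard medium (18 of 24 members, adjusted p = 0.345 with an estimated correlation), with Spry4, an inhibitor of receptor tyrosine kinase signalling, at 1.5 ± 0.17 against 25 ± 0.41 FPKM. Most interferon response genes and all tested cholesterol synthesis genes were higher than in standard medium, and most ribosomal protein genes were lower (adjusted p = 0.345, 0.631 and 0.749 with an estimated correlation). A set of genes not expressed at such levels in either other condition was high, with Capn6 at 100 ± 1.4 against 1.25 ± 0.13 FPKM and Dnmt3l at 123 ± 5.0 against 4.0 ± 0.38 FPKM.

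By limma, 7943 genes differed at an adjusted p below 0.05 (8239 at an unadjusted p below 0.05), 4842 higher and 3101 lower. The median change of all genes was 0.11 on the log2 scale, and the split was 4148 and 3794 under quantile normalization and 3906 and 4013 under median scaling. At least 2-fold differences numbered 1181, with 611 higher and 570 lower (509 and 657 under quantile normalization, 467 and 687 under median scaling). Txnip, the thioredoxin-interacting protein gene, was at 263 ± 5.7 against 11.7 ± 0.82 FPKM, and Cited1, a transcriptional coactivator gene, at 130 ± 2.4 against 10.2 ± 0.46 FPKM. Mme, the membrane peptidase neprilysin, was at 35.1 ± 0.83 against 1.58 ± 0.14 FPKM. Nodal, the ligand that Foxh1 serves, was at 17.1 ± 0.14 against 1.48 ± 0.29 FPKM. The pluripotency factor gene Pou5f1 was listed at 0 in both standard medium libraries and at 4.25 ± 0.53 FPKM with ectopic Esrrb. Slc38a4 was lowest relative to standard medium, at 0.533 ± 0.021 against 143 ± 3.4 FPKM, followed by Laptm5 at 0.871 ± 0.012 against 41.7 ± 3.2 FPKM. Surf1, a cytochrome oxidase assembly factor gene, was at 0.234 ± 0.016 against 14.1 ± 1.7 FPKM and its neighbour Surf2 at 0.280 ± 0.15 against 16.7 ± 0.57 FPKM.

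Of the self-renewal list, 16 of 22 members were lower and 4 higher (median -0.57, camera adjusted p = 7.23e-05, adjusted p = 0.394 with an estimated correlation). Duox2 was at 0.925 ± 0.15 against 35.0 ± 0.47 FPKM, Elf5 at 64.0 ± 1.2 against 180 ± 2.9 FPKM, and the chromatin organiser gene Satb1 at 2.58 ± 0.022 against 14 ± 0.030 FPKM. The FGF and ERK response list was lower in 18 of 24 members and higher in 4 (median -1.48, camera adjusted p = 7.26e-07, adjusted p = 0.345 with an estimated correlation), with Myc at 14.1 ± 1.4 against 65.8 ± 0.52 FPKM. The activin, TGF-beta and BMP list was lower in 11 of 19 and higher in 4 (median -0.44, camera adjusted p = 0.0113, adjusted p = 0.759 with an estimated correlation), with Id1, a BMP target, at 7.01 ± 0.12 against 53.8 ± 0.62 FPKM. Interferon response genes were higher in 17 of 18 (median 1.02, camera adjusted p = 2.11e-05, adjusted p = 0.345 with an estimated correlation), led by Gbp2 at 12.9 ± 1.4 against 0.896 ± 0.081 FPKM.

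All 19 cholesterol synthesis genes were higher (median 0.79, camera adjusted p = 3.61e-06, adjusted p = 0.631 with an estimated correlation), with the farnesyl diphosphate synthase gene Fdps at 121 ± 4.1 against 31.4 ± 0.17 FPKM. Oxidative phosphorylation and TCA cycle genes were higher in 24 of 32 and lower in 2 (median 0.17, camera adjusted p = 0.0023, adjusted p = 0.759 with an estimated correlation), and DNA replication genes higher in 20 of 29 and lower in 2 (median 0.30, camera adjusted p = 0.0086, adjusted p = 0.759 with an estimated correlation). Stress and unfolded protein response genes were lower in 14 of 25 and higher in 8 (median -0.53, camera adjusted p = 0.0043, adjusted p = 0.759 with an estimated correlation); the members with the smallest p included Sesn2 at 13.2 ± 0.33 against 63.1 ± 1.9 FPKM and the serine synthesis enzyme gene Psat1 at 52.6 ± 3.3 against 194 ± 4.4 FPKM. Ribosomal protein genes were lower in 29 of 31 (median -0.69, camera adjusted p = 9.82e-12, adjusted p = 0.749 with an estimated correlation), with Rpl18 at 527 ± 5.0 against 1398 ± 4.3 FPKM.

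The other 17 lists did not pass, with camera adjusted p from 0.147 to 0.991. These included giant cells (3 higher, 4 lower of 16), spongiotrophoblast (4 higher, 1 lower of 9), syncytiotrophoblast and labyrinth (8 higher, 5 lower of 19), mitosis (17 higher, 3 lower of 28), epithelial (13 higher, 5 lower of 22) and imprinted genes (7 higher, 9 lower of 21). CDK inhibitors, pluripotency, primitive endoderm, fibroblasts, mesenchymal transition, steroid hormones, glycolysis, Wnt, immediate early genes, blood and endothelium, and histones were the rest. For Wnt response and CDK inhibitors the median lay above that of all genes and the camera direction was down, and for mesenchymal transition it lay just below (-0.000144) and the direction was up. In total 9 lists passed, 0 with an estimated correlation, and counts adjusted over the list alone were the same in 20 of 26 lists, with differences of at most 2 genes. Imprinted genes included Igf2 at 2164 ± 4.8 FPKM and Phlda2, a regulator of placental size, at 256 ± 0.75 FPKM, both above standard medium (503 ± 4.7 and 38.2 ± 4.2 FPKM).

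Genes also differed by chromosome in this comparison. The median log2 change was 0.40 over the 537 tested genes of chromosome 3 (95% bootstrap interval 0.355 to 0.446) and -0.40 over the 406 of chromosome 14 (-0.481 to -0.322). The other autosomes lay between -0.13 and 0.22 as a whole, but parts of them were as far out: relative to all genes, the 20 Mb windows of chromosome 4 from 120 to 160 Mb stood at -0.56 and -0.71 (229 and 140 genes), and those of chromosome 7 from 20 to 80 Mb at -0.51, -0.67 and -0.32 (191, 91 and 35 genes). Without bFGF alone the medians of chromosomes 3 and 14 were -0.21 and -0.08. Sox2, Txnip, Mme, Fdps and Gbp2 are on chromosome 3, and Spry2, Bmp4, Zic2 and Gjb2 are on chromosome 14.

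**Figure D4:**
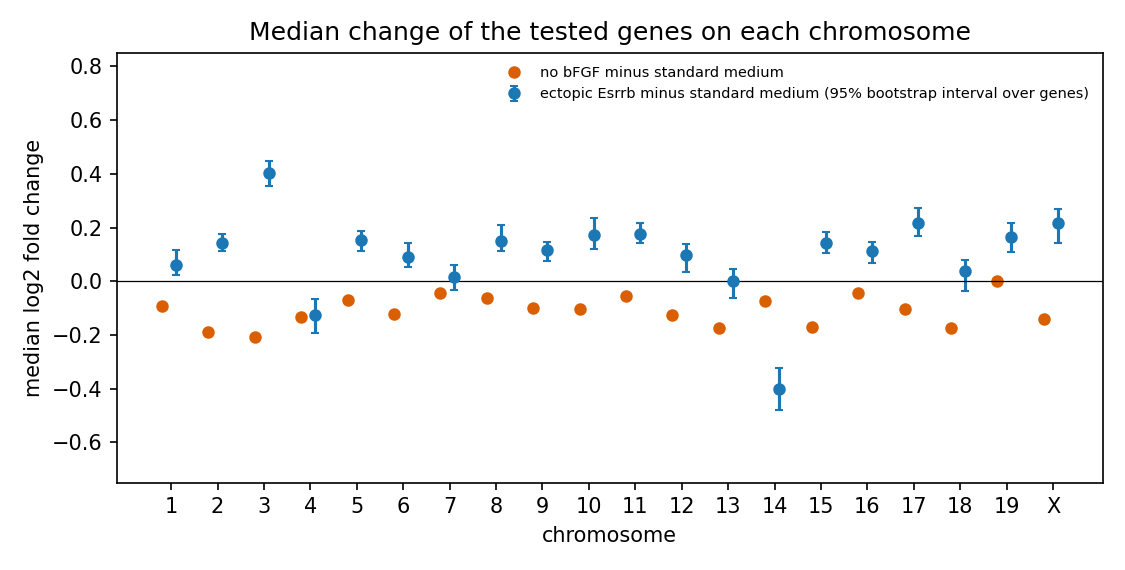
Median log2 fold change of the tested genes of each chromosome, without bFGF (orange) and with ectopic Esrrb (blue, with 95% bootstrap intervals over genes), both against standard medium. With ectopic Esrrb, chromosome 3 lies at 0.40 and chromosome 14 at -0.40, outside the range of -0.13 to 0.22 of the other autosomes.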

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

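The count of transcripts without a gene symbol, which no comparison used, was chosen after the main results were seen. Of these, 4 had at least 5 FPKM and were at least 2-fold higher without bFGF than in standard medium. They lay on mm9 at chromosome 13, 3633324 to 3651020 (3.97 ± 0.59 to 10.4 ± 0.16 FPKM), chromosome 14, 3609811 to 3650049 (0.046 ± 0.034 to 8.18 ± 0.24 FPKM), chromosome 14, 3849204 to 3889441 (0.046 ± 0.034 to 8.33 ± 0.14 FPKM), and chromosome X, 150158097 to 150175839 (2.48 ± 0.34 to 7.29 ± 0.97 FPKM). With ectopic Esrrb, 1 was at least 2-fold higher than in standard medium, the transcript on chromosome X (8.52 ± 0.19 FPKM). They were not tested, and each value is a mean of 2 libraries.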

How the results depend on the processing

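The crossed replicate block and the 2-fold counts were chosen after the data were seen; the others were set before. The counts of changed genes stayed within 1.5 times with every other scaling, filter, pseudocount, model and threshold and with each library left out. With a 2-fold change also required they were 2268, 2479 and 1181 in the 3 comparisons, and the 1181 became 1800 at a pseudocount of 0.1, and the 2268 and 2479 became 1493 and 1647 at a mean of at least 5 FPKM, with fewer genes tested. All 26 lists were tested in each comparison. With an estimated correlation, tested on 3 residual degrees of freedom, 0, 0 and 0 lists passed. With fry, which does not compare a list with other genes, 23, 25 and 24 did. Leaving out each library in turn gave 9 to 15 lists without bFGF. The share of lower genes that moved back was 93.1% at a mean of at least 5 FPKM, 87.4% under quantile normalization, 87.0% under median scaling, 86.2% at an adjusted p below 0.01, 79.5% with changes of any size and 87.4% to 92.3% with a library left out. For higher genes it was 84.8% and 88.4% at pseudocounts of 0.1 and 0.5, 92.9% under quantile normalization, 94.1% under median scaling, 88.7% at an adjusted p below 0.01, 62.5% with changes of any size and 88.0% to 91.2% with a library left out. Genes that moved at least 2-fold both ways were 59.6% of the lower and 61.2% of the higher genes; picked with 1 no bFGF library and measured against the other they were 55.3% and 59.8%, and 64.4% and 56.5%. The fibroblast list did not pass with no filter (camera adjusted p = 0.186), with the highest transcript per symbol (0.0586) or with 2 groups in the fit (0.0634), nor did activin (0.236, 0.0526 and 0.0634; 0.125 at a mean of at least 5 FPKM) and, with 2 groups or that mean, oxidative phosphorylation (0.0634 and 0.0685). Among genes named in the text, the log2 change turned sign without bFGF for Med22 (0.13) and Mprip (-0.36) with the highest transcript per symbol, Rpl18 (0.089) under quantile normalization and Cited1 (-0.27 to 0.20 with a library left out, positive without no bFGF replicate 1). It turned with ectopic Esrrb against no bFGF for Mprip (0.80) and Slk (0.71) with the highest transcript and, under median scaling, for Igf2 (-0.24), Klf5 (-0.17), Rpl7a (-0.035) and Utf1 (-0.15). Eef1a1, at the top of every library, had a change of 0 in all 3 comparisons under quantile normalization. Sign changes are listed only where the gene was called in the main fit or under the other setting. Of the other recomputed values of these genes, 55 kept direction but lost the call and 20 gained one. The remaining 5010 kept the call, and kept direction where the gene was called. Uncalled genes among them may have turned sign. The causes were not tested. Where 1 library was left out, the lone sample of its group was assumed to vary like the other groups. Requiring an OK status removed nothing and says nothing about stability.

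Deviations of same-numbered libraries correlated at 0.029, -0.039 and -0.304, so the replicate numbers were not taken to pair them. With the number as a replicate block, 8846, 9091 and 7854 genes changed, and with the numbers of the ectopic Esrrb libraries crossed 9088 changed in the second comparison. The block ended the call of oxidative phosphorylation genes without bFGF (camera adjusted p = 0.0525) and changed no other list call.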

Other observations

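Among the genes tested, some moved with ectopic Esrrb beyond either other condition. Of the 2479 genes that changed at least 2-fold against no bFGF, 2179 had changed in the opposite direction without bFGF, 98 in the same direction, and 202 had not passed the test there. Named after their values were seen, 12 genes with at least 5 FPKM with ectopic Esrrb were at least 10-fold higher there than in both other groups, as a ratio of mean FPKM with nothing added. They included Scube3, a secreted signalling protein gene, at 43.9 ± 1.1 FPKM against 2.77 ± 0.18 in standard medium and 3.63 ± 0.24 without bFGF, and Spsb4, a ubiquitin ligase adaptor gene, at 18.8 ± 0.57 against 1.21 ± 0.16 and 1.32 ± 0.13 FPKM. At least 10-fold lower by the same ratio were 8 genes, of those with at least 5 FPKM in both other groups, among them Arhgef16, a guanine nucleotide exchange factor gene, at 0.062 ± 0.047 against 9.04 ± 1.0 and 49.4 ± 1.0 FPKM, and Pcsk6, a protease gene that processes nodal, at 0.551 ± 0.028 against 9.67 ± 0.026 and 6.42 ± 0.95 FPKM. Arhgef16 and Pcsk6 lie in 20 Mb windows of chromosomes 4 and 7 that were lower than standard medium (-0.71 and -0.32 relative to all genes). Slc38a4, Surf1 and Surf2, also among the 8, lie in windows near all genes (0.06 on chromosome 15 and 0.009 on chromosome 2). Mme and Txnip, among the 12, lie on chromosome 3 in windows at 0.27 and 0.34. Effects on single genes were not separated from effects on these regions.

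Single members of lists that did not pass also moved far. Slc2a3, a glucose transporter gene, was at 63.8 ± 1.6 FPKM in standard medium, 33.3 ± 1.6 without bFGF and 344 ± 2.4 with ectopic Esrrb, and the hexokinase gene Hk1 at 32.2 ± 0.53, 12.5 ± 0.23 and 94.6 ± 0.26 FPKM. Vim, an intermediate filament gene of mesenchymal cells, was at 37.9 ± 1.6, 7.85 ± 0.16 and 115 ± 1.5 FPKM. Not restored with ectopic Esrrb were Klf5, a Krüppel-like factor gene, at 91.9 ± 1.1, 24.9 ± 0.75 and 26.0 ± 0.41 FPKM, and Utf1, a chromatin protein gene, at 84.3 ± 4.8, 24.0 ± 2.6 and 25.3 ± 0.65 FPKM. Neither passed the limma test between the last 2 groups (adjusted p = 0.26 and 0.38).

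Of the tests below, the count of windows on other autosomes, the test of the neighbours of Surf1 and Surf2 and that of transcript shares between single libraries were chosen after the results were seen, as were all values on the interferon genes, and chromosomes 3 and 14 were picked because their medians stood out. With ectopic Esrrb, genes of chromosome 3 lay above and those of chromosome 14 below standard medium as a whole, in both replicates (medians 0.403 and 0.397, and -0.408 and -0.414). Sets of other genes matched on expression and transcript length were as far out in a share of 0.0001, the smallest that 10000 sets can give. Of the 20 Mb windows, 84.6% (11 of 13) lay on the side of their chromosome, the outcome set beforehand as speaking against a few gene clusters. Both chromosomes were picked on these same values, so these outcomes were likely from the start and do not decide whether gene clusters are the cause. Over genes that hardly changed without bFGF, chromosome 3 stood 0.293 above the other autosomes and chromosome 14 stood at -0.446 relative to them, as a gain of chromosome 3 and a loss of chromosome 14 in part of these cells could give. The pattern was not particular to these chromosomes, however. Of the 114 windows on other autosomes 7 lay at least 0.3 from all genes, all of them below, and 5 of these formed blocks on chromosomes 4 (120 to 160 Mb) and 7 (20 to 80 Mb). Whether copy number differs in any of these places was not measured and would need DNA. Along chromosome 14 the windows stood at -0.64, -0.37, -0.23, -0.75 and -1.26 relative to all genes. The last held 23 genes and stood at -0.41 without bFGF, where the first stood at 0.37. An even loss of the whole chromosome would not by itself give this unevenness. The first 3 windows of chromosome 3 stood at 0.10, -0.12 and -0.07 relative to all genes, against 0.27 to 0.43 beyond 60 Mb, so part of the chromosome may be involved; 1 extra copy in all cells would give 0.585, and biological effects of Esrrb on both chromosomes stay open.

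Surf1 and Surf2, whose ends overlap at chromosome 2, 26768898 to 26772050 and 26771941 to 26775690 (mm9), were near 0 with ectopic Esrrb. Their neighbours Surf4, Surf6, Med22 and Rpl7a did not follow: their median change against no bFGF lay -0.0723 from that of all genes, which argues against loss of a larger region. What stays open is 2 separate falls, or a local event at the pair in the cells that carry ectopic Esrrb. Such an event could be a deletion or an insertion, among others. Which of these took place could not be examined in expression values. The overlapping ends also leave the division of reads between both genes uncertain.

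A hypothesis on transcript use was tested on 3983 transcripts of 1526 genes. Without bFGF, 108 changed their share of the gene's FPKM by at least 25 points between group means. Up to 76 shifted as far between replicates of a group, 0.704 of that number, and this test, whose outcomes were set before it was run, favoured chance in the division of reads. It compared single libraries with group means; between single libraries of the same number 177 shifted without bFGF against standard medium, of which 76 is 0.429, still within the range set for chance. A further test was added after this outcome was seen. Of the 103 genes picked with replicates 1 of both groups, 83.5% shifted the same way between replicates 2, and of the 98 picked with replicates 2, 83.67% did so between replicates 1, which argues against chance as the whole cause. Only 41 and 42 of them shifted by 25 points again, so chance may account for a large part of the counts. Of genes picked with 1 no bFGF library and measured against the other, 70 of 81 and 69 of 91 moved the other way with ectopic Esrrb. The epithelial splicing regulator genes Esrp1 and Esrp2 rose without bFGF and were lower with ectopic Esrrb than without it. Without bFGF Esrp2 had a log2 change of 2.19 (7.91 ± 0.53, 39.6 ± 4.1 and 8.25 ± 0.48 FPKM in the 3 groups). A part for them may be considered, though no test tied them to these transcripts. For Fgfr2, the FGF receptor gene of these cells, 1 transcript held 78.4% ± 1.1 in standard medium, 44.9% ± 3.8 without bFGF and 85.9% ± 0.32 with ectopic Esrrb; Slk (86.3%, 44.5% and 91.8%) and Mprip (86.3%, 48.0% and 96.2%) each had a transcript with a like course.

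For the interferon list, explanations were tried and then set aside because the tests decided nothing, and only values are given. The list's median was 1.06 and 1.00 FPKM in standard medium, 8.95 and 9.04 FPKM without bFGF and 4.87 and 4.59 FPKM with ectopic Esrrb. The summed FPKM of 7 leukocyte genes without bFGF was 0.482 of that in standard medium, a ratio that rests on Laptm5, while Csf1r and Cd68 (4.86 ± 0.43 and 10.1 ± 0.38 FPKM) rose and Ptprc, Tyrobp, Fcer1g and Lyz2 stayed at or below 0.149 FPKM without bFGF.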
